A study of Homo sapiens with 4 samples.

How the data were processed

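Chromatin of primary human corneal epithelial cells was sequenced as 4 libraries of single-end 50-base reads, 1 each for H3K4me1, H3K4me3, H3K27ac and Input. Per the labels' protocols, the cells were grown at 37 degrees in 5% CO2 and fixed at about 50% confluence. The labels name 1 histone antibody for each ChIP library, whereas the shared text on extraction names a Grhl3 antibody. The groups here follow the antibody named for each sample. The labels number no replicates, and nothing in them says how many cultures or donors the cells came from.

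The submitters' processing notes name Bowtie 0.12.7, bedtools 2.11.2, SICER 1.1 and the hg19 build, without giving their roles or settings. SICER joins enriched windows into islands and compares each with a control library. The deposited files were 1 island list for each mark, with no header, and the columns were read by the SICER layout. The deposited read counts, raw and whole, give the ChIP reads and the control reads in each island. The deposited fold is a ratio: it equalled the ChIP count over the control count times 1 constant for each list in every island with a control read (relative tolerance 1e-06). That constant was 1.21 for H3K4me1, 2.25 for H3K4me3 and 2.04 for H3K27ac. If it is the ratio of library sizes, as in SICER, the ChIP libraries held 82.6%, 44.5% and 49.0% of the reads of the control. The deposited p-value and FDR of each island were taken as given. The names of the lists give an FDR of 0.05, but the highest FDR in any list was 0.000370379.

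Other steps were read from the values and are stated by no label. Every island edge lay on a grid of 200 bases. The smallest gap between islands was 400 bases in the H3K4me3 list and 600 in the others, which fits merging across 200 and 400 bases. The lowest fold was 4.00 in the H3K4me3 list and 2.00 in the others, so a minimum fold appears to have been applied, and not the same for all marks. The wider merging can lengthen H3K4me1 and H3K27ac islands relative to H3K4me3, and the higher minimum removes weak H3K4me3 islands. Both affect which islands overlap. That the control column is the Input library is inferred, since Input was the only control among the samples. The 3 lists used 1 control: islands with identical ends had equal control counts in 1700 of 1700 pairs of H3K4me1 and H3K4me3, in 1700 of 1700 of H3K4me1 and H3K27ac, and in 702 of 702 of H3K4me3 and H3K27ac. Part of any overlap may therefore come from the shared control. It could not be split, and no overlap without enrichment could be simulated from control reads given only inside islands.

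Analysis was restricted to the 22 autosomes, so that nothing about the donor is shown. The span of each chromosome was taken up to the last island on it, 2879 Mb in all. It includes unassembled stretches, into which shifts can move islands, so densities per Mb were counted from the first to the last island. Total library sizes are not given in the sources used here. Depth is therefore given as reads inside islands, with a median for each island of 275 ChIP reads for H3K4me1, 895 for H3K4me3 and 260 for H3K27ac, and 96, 128 and 144 control reads. The fewest ChIP reads in an island were 34, 21 and 27. In the 20 H3K4me3 islands with 0 control reads the deposited fold has no real denominator, and a bound against 3 counts for the island is printed instead. Reads carry no molecular identifiers, so intervals and bounds cover counting error only.

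An island was counted as shared when at least 1 base overlapped an island of another mark. The share was compared with 1000 circular shifts of the other list along each chromosome, one-sided, with a smallest possible p of 0.001. All 6 directions were tested and all gave that p, so Benjamini-Hochberg adjustment leaves it at 0.001. Candidate enhancers were H3K27ac islands that overlapped H3K4me1 and no H3K4me3. Differences of medians between classes of islands were tested by 1000 rotations of the class labels along the genome, two-sided. Candidate enhancers with gaps of at most 10 kb were joined into domains and ranked by ChIP reads minus control reads, the control divided by the constant of the list. Unscaled subtraction had been planned, but it ignores the unequal library sizes. Intervals for differences of shares and for correlations came from 1000 draws of whole chromosomes with replacement. Islands are not independent replicates, and every test describes these libraries, not the cells of other cultures.

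The islands named were chosen by a rule adapted from one fixed before the data were examined. For each mark these are the 10 islands with the highest fold among those with at least 100 ChIP reads and the 10 widest, plus the 20 largest domains. The text prints those at the top of each ranking and a few others with the highest values, chosen after their values were seen, and summarises the rest. The rule as planned also named the nearest genes and 8 genes of the cornea. The gene table used here is on GRCh38, positions cannot be carried between builds here, and no hg19 genome sequence or annotation was used. Therefore 5 planned results were not run: islands at transcription start sites, genes marked at their start, gene lists at starts, gene lists and candidate enhancers, and motifs in candidate enhancers. The definition of candidate enhancers dropped its distance from gene starts for the same reason. Classes by H3K4me3 islands stand in for classes by gene starts throughout.

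The alternatives planned were an FDR of at most 0.001, a fold of at least 4 in every list, an overlap of at least 50% of the shorter island, equal numbers of islands for each mark, random placement in place of shifts, and no joining of domains. Added after seeing the data were moving a list by 50 to 500 kb, leaving out islands with under 10 control reads per kb, a fold of at least 4 for H3K27ac alone, a fold of at least 4 in the class tests, and classes set by whether the central window of an island was covered. The tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. They were first tested on simulated data, with 40 pairs of lists for each case and 200 shifts for each pair. For independent lists the mean ratio of observed to shifted overlap was 0.991, and 2 of 40 pairs gave p under 0.05. With planted overlap 40 of 40 pairs did. The overlap differed from a brute-force count in 0 islands. The rotation test gave p under 0.05 in 0 of 40 simulations without a difference and in 40 of 40 with shifted medians. The simulated islands were spread at random, without clusters or a shared control, and the values given to the rotation test were independent along the genome. The simulations therefore do not show how the tests behave on clustered lists such as these.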

Results

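Primary human corneal epithelial cells, cultured from the layer that covers the front of the cornea, were profiled by ChIP-seq for 3 modifications of histone H3. There was 1 library for each of H3K4me1, H3K4me3 and H3K27ac and 1 Input library. By general knowledge, H3K4me3 marks the promoters of active and poised genes, H3K4me1 marks enhancers and the flanks of promoters, and H3K27ac marks promoters and enhancers in use. The comparison set by the design was where each mark lay along the genome of these cells and how far the marks shared their positions. Each mark was available as a list of islands, which are stretches of 200-base windows enriched over a control. Positions are in hg19 and cover the 22 autosomes. Because each mark had 1 library, no value has a spread between cultures. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and treat islands as independent, which neighbouring islands are not. The range over autosomes is therefore given beside the main shares.

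H3K4me1 was the most widespread mark. It formed 111937 islands over 279.0 Mb, or 9.69% of the autosomal span. H3K27ac formed 29208 islands over 100.9 Mb (3.51%), and H3K4me3 formed 24665 islands over 57.4 Mb (1.99%). H3K4me3 was the most strongly enriched, with a median fold over control of 16.02 (quartiles 6.54 and 26.7). The median fold was 3.56 for H3K4me1 (2.75 and 4.69) and 3.20 for H3K27ac (2.46 and 4.63). Median island widths were close, at 1800 bases for H3K4me1, 2000 for H3K4me3 and 2400 for H3K27ac. The ChIP reads inside islands numbered 62666949 for H3K4me1, 33294991 for H3K4me3 and 12283446 for H3K27ac. Brought to the depth of the control with the factor in each list, these became 75.9, 74.8 and 25.1 M (mega) reads. At that depth the H3K4me1 islands held 3.03 times the reads of the H3K27ac islands on 279.0 against 100.9 Mb, and the H3K4me3 islands held 2.98 times on 57.4 Mb. Pooled over islands, the fold was 4.45 for H3K4me1, 20.02 for H3K4me3 and 3.8 for H3K27ac. The lowest fold was 2.00 in the H3K4me1 and H3K27ac lists and 4.00 in the H3K4me3 list. With a minimum fold of 4 in every list, 43333 H3K4me1 and 9823 H3K27ac islands remained.

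Nearly all H3K4me3 and H3K27ac islands of the deposited lists lay in chromatin that also carried H3K4me1. Of the H3K4me3 islands, 97.7% shared at least 1 base with an H3K4me1 island (95% interval 97.6 to 97.9; 95.9 to 99.2 over autosomes). Of the H3K27ac islands, 98.6% did so (98.5 to 98.7; 96.98 to 99.2 over autosomes). When the H3K4me1 list was shifted around each chromosome, the mean shares were 18.0% and 20.4%. In the deposited lists H3K4me3 and H3K27ac shared fewer islands with each other than with H3K4me1, a ranking that depended on how many islands entered, as given below. An H3K27ac island overlapped 66.2% of the H3K4me3 islands (65.7 to 66.8; 60 on chromosome 13 to 72.2 on chromosome 19), 10.5 times the 6.29% of the shifts. In the other direction, 54.1% of the H3K27ac islands overlapped H3K4me3 (53.5 to 54.6; 45.8 on chromosome 4 to 74.0 on chromosome 19), 10.4 times the 5.19% of the shifts. From the side of H3K4me1, 20.9% of the islands overlapped H3K4me3 and 25.5% overlapped H3K27ac, against 4.11% and 5.89% in the shifts. All 6 shares lay above every one of 1000 circular shifts (one-sided permutation p = 0.001 each, the smallest that the shifts can give). Against moves of 50 to 500 kb, which stay in the same neighbourhood, the ratios were lower, at 6.24 for H3K4me3 with H3K27ac, 6.27 in the other direction and 2.81 to 3.58 for the other 4 (permutation p = 0.001 each). These tests concern the placement of the lists in these libraries. The shares themselves depended on how many islands entered: with a minimum fold of 4 in every list, 75.03% of the H3K4me3 and 70.8% of the H3K27ac islands overlapped H3K4me1, 34.7% of the H3K4me3 islands overlapped H3K27ac and 84.5% of the H3K27ac islands overlapped H3K4me3, and 40.3% and 16.2% of the H3K4me1 islands overlapped H3K4me3 and H3K27ac. Equal lists of 24665 islands were taken by lowest FDR and, among islands of equal FDR, by higher fold. In these, 63.0% of the H3K4me3 and 64.8% of the H3K27ac islands overlapped H3K4me1, while 58.1% and 61.7% of the H3K4me1 islands overlapped H3K4me3 and H3K27ac. There 62.9% of the H3K4me3 islands overlapped H3K27ac and 60.5% of the H3K27ac islands overlapped H3K4me3, close to the shares with H3K4me1.

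Any of the 3 marks covered 288.0 Mb. H3K4me1 alone took 58.6% of these bases, H3K4me1 with H3K27ac took 18.9%, all 3 marks together took 13.4%, and H3K4me1 with H3K4me3 took 6.06%. H3K4me3 without any other mark took 0.296% and H3K27ac without any other mark 2.61%. Counted by islands, 75910 H3K4me1 islands (67.8%) met neither of the other marks. These were short, with a median of 1400 bases, and weak, with a median fold of 3.12. The composition rests on the deposited lists, with a lowest fold of 2.00 for H3K4me1 and H3K27ac and 4.00 for H3K4me3. No alternative was run for it, and the overlap shares above changed with the number of islands.

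**Figure D1:**
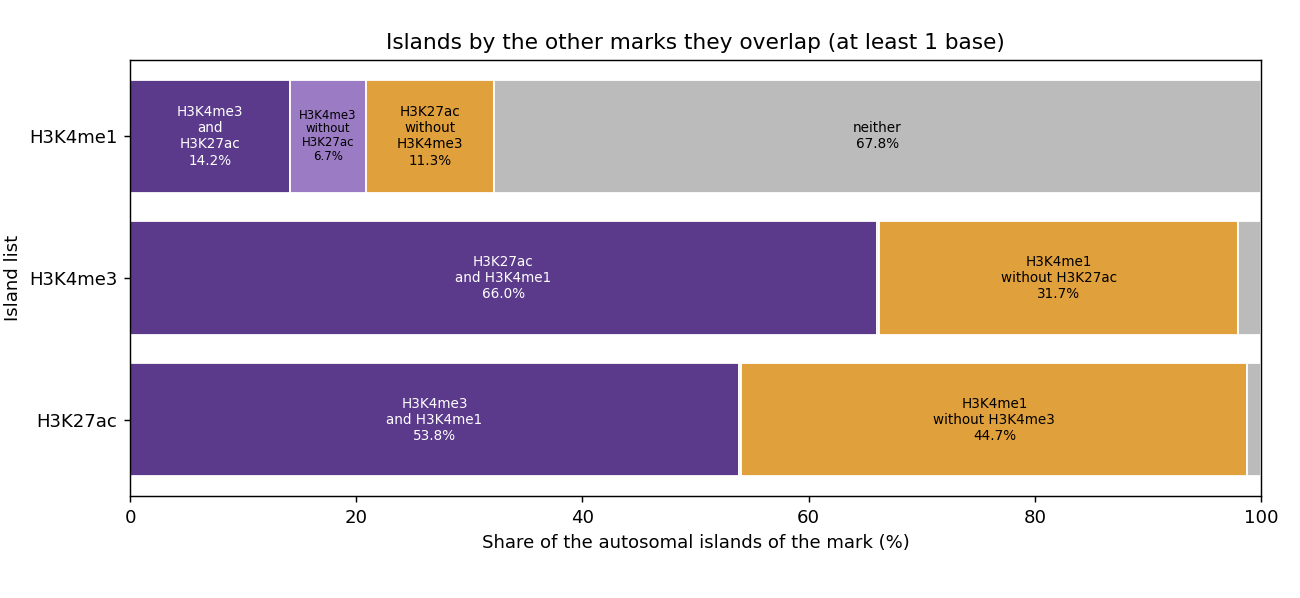
Share of the autosomal islands of each mark (horizontal axis, percent) that overlapped the other marks by at least 1 base, with 1 bar for each island list of 1 library. Of the H3K4me1 islands 67.8% met neither other mark, whereas 66.0% of the H3K4me3 and 53.8% of the H3K27ac islands met both; in the H3K4me3 and H3K27ac bars the unlabelled slivers are islands that met only the other of these marks (0.211% and 0.205%) and, in grey, neither (2.04% and 1.20%).

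H3K4me3 islands that also carried H3K27ac were stronger and wider than those that did not. The 16340 H3K4me3 islands with H3K27ac had a median H3K4me3 fold of 22.7, against 8.14 for the 8325 without. Their median width was 2600 bases against 1200, or 2.17 times as wide. Both differences were larger than in every one of 1000 rotations of the labels along the genome (two-sided permutation p = 0.001 each, the smallest possible). Since a wider island meets another more readily by 1 base, the central window was also used to set the classes, and the difference in width was again 1400 bases (permutation p = 0.001). That check deals with overlap only. Without H3K27ac means that no H3K27ac island was called, at a lowest fold of 2.00, and not that acetylation was absent. Whether calls failed more often at weak or narrow sites was not tested. In the narrowest decile of the H3K4me3 islands 31.8% carried H3K27ac (29.9 to 33.7), and the share rose to 96.8% (96.0 to 97.5) in the widest decile; by the central window alone the shares were 31.4% and 91.9%. By fold the course was not even. The share fell from 52.0% in the weakest decile to 37.7% (35.8 to 39.6) in decile 4, at folds of 7.60 to 11.04. It then rose to 96.6% in decile 9 and was 91.3% in the strongest decile. Of the 100 islands with the highest fold, 90 had under 10 control reads per kb. All H3K4me3 islands with so sparse a control, 184 in number, carried H3K27ac in 6.52%. Whether they account for the lower share in the strongest decile was not tested. A further 7821 H3K4me3 islands (31.7%) carried H3K4me1 without H3K27ac, and 504 (2.04%) carried neither.

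**Figure D2:**
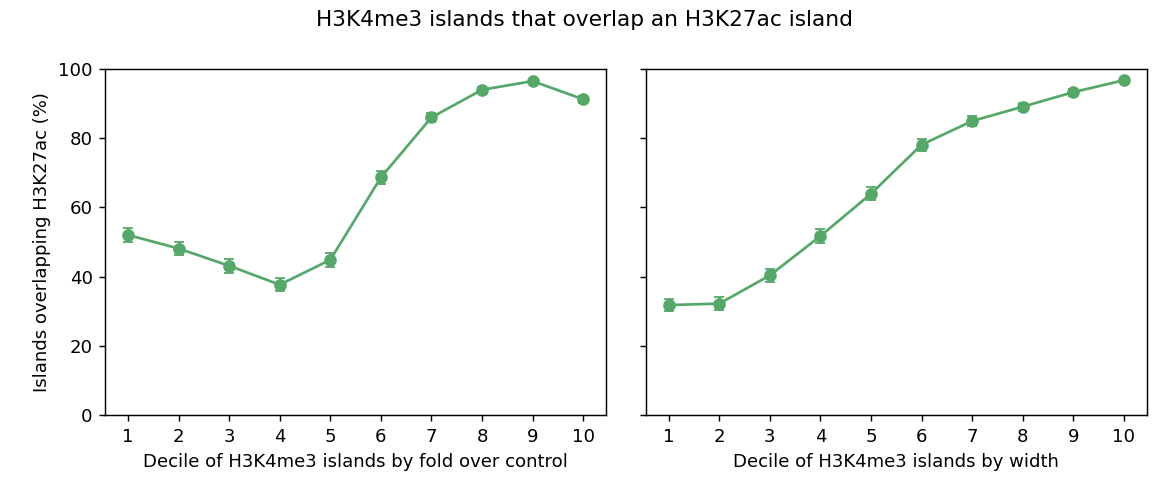
Share of H3K4me3 islands that overlapped an H3K27ac island (vertical axis, percent), in deciles of the H3K4me3 list by fold over control (left) and by width (right), from lowest to highest. Points are shares of about 2467 islands of 1 library and bars are exact 95% binomial intervals; by width the share rises from 31.8% to 96.8%, and by fold it dips to 37.7% in decile 4.

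The widest H3K4me3 islands carried all 3 marks. All 10 overlapped both H3K4me1 and H3K27ac, and they spanned 17.2 to 24.4 kb at folds of 10.7 to 33.2. The widest lay on chromosome 11 from 826801 to 851200, with 12448 ChIP and 2055 control reads and a fold of 13.6. It lay wholly inside an H3K4me1 island of fold 8.08 and an H3K27ac island of fold 3.51. On the same chromosome, the island from 31824001 to 31844800 (20.8 kb) reached a fold of 30.4 with 16907 reads, and H3K27ac covered all of it at a fold of 8.93. The island on chromosome 15 from 96867401 to 96885400 (18 kb) had a fold of 33.2, the highest of the 10, and the one on chromosome 6 from 10402601 to 10422200 (19.6 kb) a fold of 29.9. The islands of highest H3K4me3 fold were narrow and lay over a sparse control. The 10 with the highest deposited fold and at least 100 ChIP reads were 600 to 1400 bases wide, 0 of them overlapped H3K27ac and 2 overlapped H3K4me1. Their control counts were 0 to 7 reads. Of the 10, 9 had at most 3 control reads, so neither their order nor their place among the 10 is established. Of these, 3 had 0 control reads and lay at least 141-fold, 98.1-fold and 89.8-fold above control against a floor of 3 counts per island. The first, on chromosome 2 from 86947201 to 86948600, had 188 ChIP reads.

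The other lists had extremes of their own. The widest H3K27ac island lay on chromosome 9 from 137205201 to 137285800 (80.6 kb) with a fold of 2.72. It contained the widest H3K4me1 island, from 137218601 to 137284400 (65.8 kb), with a fold of 6.45. All 10 of the widest H3K27ac islands overlapped H3K4me3, and so did 9 of the 10 widest H3K4me1 islands. The exception was the H3K4me1 island on chromosome 3 from 13861801 to 13910000, which carried H3K27ac over 98.3% of its bases and no H3K4me3 island. Islands this wide meet another by 1 base readily. H3K4me3 covered 10.1% to 59.7% of the bases of the 10 widest H3K27ac islands and 7.90% to 68.6% of the 9 H3K4me1 islands. By fold, the first H3K27ac island lay on chromosome 20 from 52208601 to 52211800, at 28.6 with 378 ChIP and 27 control reads (8.44 per kb). The second, on chromosome 6 from 42749401 to 42752200, had 1090 ChIP and 94 control reads and a fold of 23.7. Of the 10 H3K27ac islands with the highest fold, 4 had under 10 control reads per kb, the first included, and 6 overlapped H3K4me1. Of the 10 H3K4me1 islands with the highest fold, 9 overlapped H3K4me3, 1 overlapped H3K27ac, and their control counts were 2 to 13 reads.

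Along wide H3K4me3 islands both other marks were more common inside than outside. In the 6973 H3K4me3 islands of at least 3 kb, H3K4me1 islands covered 97.2% of the central windows and 59.7% of the windows in the first 1 kb beyond the edges. Outside windows that lay in another H3K4me3 island were left out for both marks. The difference was 37.5 percentage points (SD over autosomes 3.75), and it was above 0 on 22 of 22 autosomes. H3K27ac covered 89.9% of the central windows and 29.7% of those outside, a difference of 60.2 points (SD over autosomes 7.18), also above 0 on 22 of 22. The marks differed in how coverage changed inward. H3K4me1 was already at 97.5% in the first window inside the edge, where H3K27ac stood at 53.2%. H3K4me1 coverage was highest at 500 bases inside (99.1%) and slightly lower at the centre (97.2%), whereas H3K27ac coverage kept rising inward to 89.9%. An island records that reads passed the caller's limits, not their height, so coverage near 100% does not exclude a weaker signal at the centre.

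**Figure D3:**
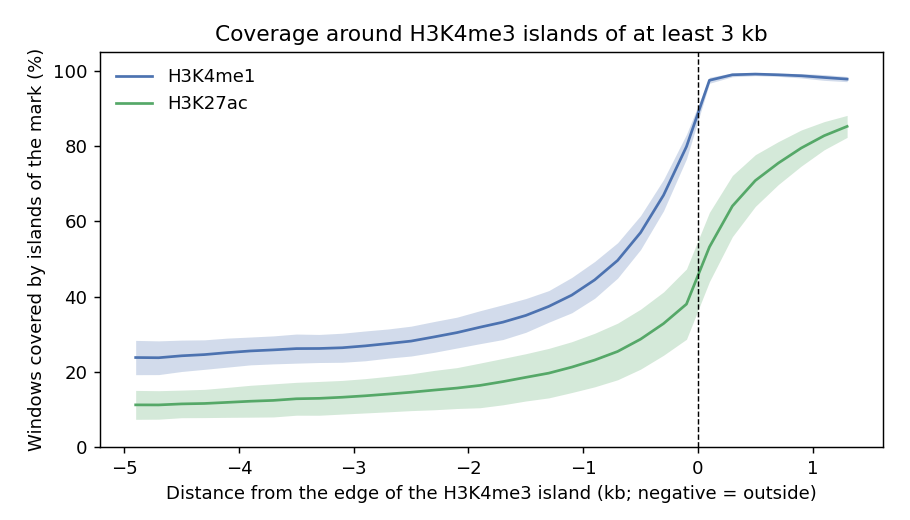
Share of 200-base windows covered by H3K4me1 or H3K27ac islands (vertical axis, percent) by distance from the edge of the 6973 H3K4me3 islands of at least 3 kb (horizontal axis, kb, negative outside, both edges pooled). Lines are shares over all windows, except that outside windows in another H3K4me3 island were left out, and bands are 1 SD over the 22 autosomes. H3K4me1 coverage climbs to 97.5% in the first window inside. H3K27ac coverage climbs more slowly, from 53.2% there to 85.2% in the last inner window drawn.

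A total of 13069 H3K27ac islands (44.7%, 44.2 to 45.3; 23.05 to 52.9 over autosomes) overlapped H3K4me1 and no H3K4me3 island, the usual marking of an active enhancer, and are called candidate enhancers below. They covered 38.1 Mb. Acetylation was weaker in them than in H3K27ac islands with H3K4me3. The median H3K27ac fold was 2.68 in candidate enhancers against 4.14 in the 15788 islands with H3K4me3, and the median width was 2200 against 2600 bases. Both differences exceeded all 1000 rotations of the labels (two-sided permutation p = 0.001 each). Median ChIP reads were 74.6 against 130 per kb, and median control reads also differed, at 55.9 against 65.5 per kb. Among H3K4me1 islands without H3K4me3, the 12687 with H3K27ac had a median H3K4me1 fold of 4.52 and a width of 3000 bases, against 3.12 and 1400 bases in those without (permutation p = 0.001 each in the same test). No H3K4me3 here means no island of fold 4 or more, the lowest value in that list. With a minimum fold of 4 in every list the difference in H3K4me1 fold was 0.629 in place of 1.40, 1293 candidate enhancers remained, and the difference in H3K27ac width turned to -200 bases (permutation p = 0.0539). With classes set by the central window the difference in width was 200 bases (permutation p = 0.001).

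Joined within 10 kb, the candidate enhancers formed 10347 domains, of which 8383 held 1 island and 1964 held more. The 20 largest by reads above the scaled control were 22.6 to 90.8 kb long and lay on 11 chromosomes. They made up 0.193% of the domains and held 4.56% of the reads above control. Their excess was 3306 to 9157 reads, against a median of 108 over all domains. The largest lay on chromosome 12 from 52531401 to 52570400 (39 kb, 3 islands), with 10593 ChIP reads, 2931 control reads and a fold of 7.38. H3K4me1 covered 84.6% of it. The next were on chromosome 21 from 44896001 to 44945400 (fold 4.98, excess 7998 reads), on chromosome 1 from 209527201 to 209593200 (fold 5.66, 7898 reads) and on chromosome 3 from 13862001 to 13910000 (fold 4.70, 7343 reads). The domain on chromosome 11 from 119541801 to 119578400 was a single H3K27ac island of 36.6 kb inside 1 H3K4me1 island. The longest was on chromosome 10 from 105494601 to 105585400 (90.8 kb, 8 islands, fold 2.798). It was 1 of 2 domains among the 20 with an H3K4me3 island between their candidate enhancers. Which genes these regions belong to was not analysed here.

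**Figure D4:**
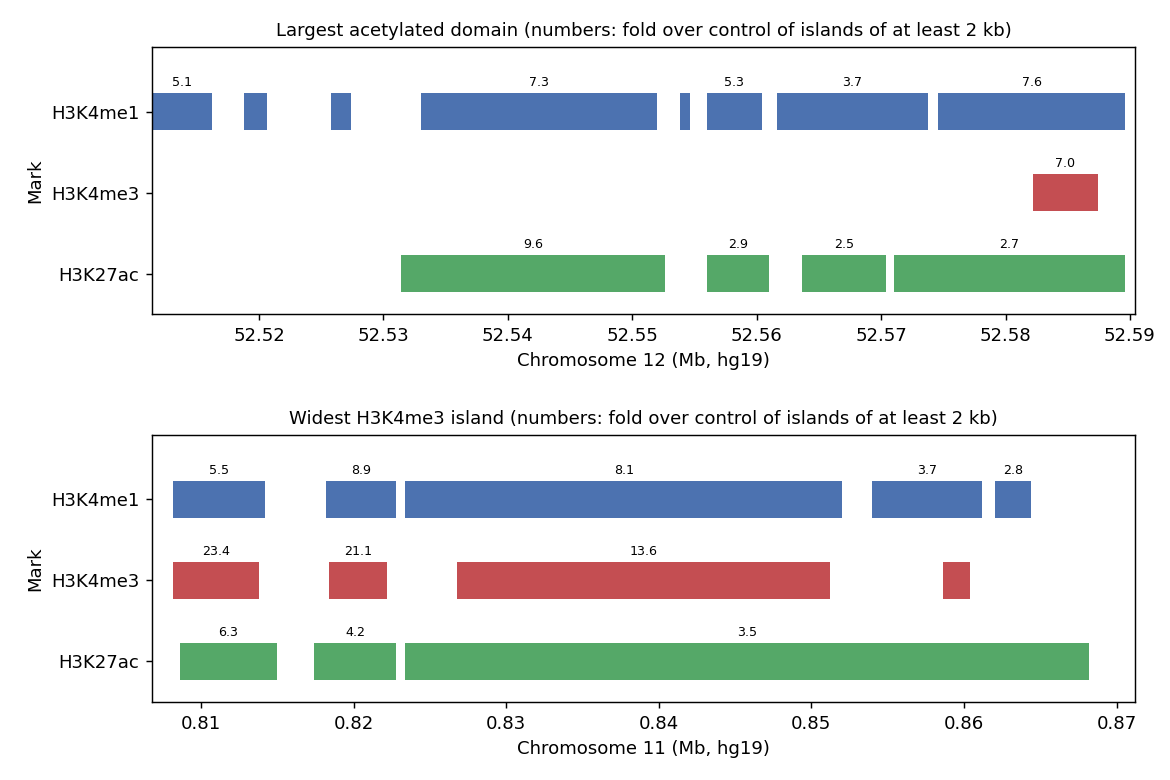
Islands of the 3 marks (rows) along chromosome 12 around the largest domain of candidate enhancers (top) and along chromosome 11 around the widest H3K4me3 island (bottom), drawn to scale in Mb of hg19, with the fold over control above islands of at least 2 kb. In the top map the H3K27ac island from 52531401 to 52552600 has a fold of 9.56 and no H3K4me3 island; the H3K27ac island from 52571001 to 52589600 is not part of the domain because it overlaps H3K4me3.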

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

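The class tests with a minimum fold of 4, the moves by 50 to 500 kb, the limit of 10 control reads per kb, the fold of at least 4 for H3K27ac alone and the classes set by the central window were chosen after seeing the data. All 6 overlaps kept their direction and lay above every permutation under each of 7 settings (42 of 42), at 2.81 to 15.8 times the expected share. The lowest ratios, 2.81 to 6.27, came from moving a list by 50 to 500 kb, which keeps it in the same neighbourhood. The FDR limit of 0.001, which is 1 of these 7 settings, removed no island, so its results repeat the main ones and it tested nothing. A fold of at least 4 in every list left 43333 of 111937 H3K4me1 islands, 9823 of 29208 H3K27ac islands and 1293 of 13069 candidate enhancers, which follows from the lower minimum in those lists; applied to H3K27ac alone it left 1521. In the same setting the difference in H3K27ac width between islands with H3K4me3 and candidate enhancers turned from 400 to -200 bases (permutation p = 0.0539), and the cause was not tested. The difference in H3K27ac fold kept its direction there at 1.09 (permutation p = 0.001). The differences of fold and width between H3K4me3 islands with and without H3K27ac, and between H3K4me1 islands without H3K4me3 split likewise (fold 0.629 against 1.40 at a fold of at least 4), kept direction and threshold under a fold of at least 4, without low-control islands and with classes set by the central window, as did the differences in H3K27ac fold and width in the last of these. Candidate enhancers numbered 13091 with 50% overlap and 13072 without low-control islands. Of the 20 largest domains, 16 overlapped one of the 20 under a fold of at least 4, and 15 did so without joining. The alternatives of the 5 planned results that were not run, and those on the distance to gene starts, were not run either. No paired analysis was possible because each mark had 1 library, and no library could be left out. If the constants are ratios of library sizes, the H3K4me1 library was the deepest, at 82.6% of the control against 44.5% for H3K4me3 and 49.0% for H3K27ac; which weak islands more reads would add was not tested.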

Other observations

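The marks were spread unevenly over the chromosomes, and H3K4me3 most of all. Counted between the first and the last island of a chromosome, H3K4me3 islands ranged from 5.48 per Mb on chromosome 4 to 26.9 per Mb on chromosome 19, a ratio of 4.91. H3K27ac islands ranged from 7.15 to 24.8 per Mb on the same chromosomes (3.46 times), and H3K4me1 islands from 31.7 on chromosome 4 to 58.9 on chromosome 22 (1.86 times). Candidate enhancers varied least, from 3.67 per Mb on chromosome 16 to 6.14 on chromosome 15 (1.67 times). Their definition leaves out H3K27ac islands that overlap H3K4me3, which were 74.0% on chromosome 19 and 45.8% on chromosome 4. The evenness and the counts for each H3K4me3 island given next are therefore partly set by the definition. Unassembled stretches inside chromosomes were not taken out. There were 0.212 candidate enhancers for each H3K4me3 island on chromosome 19 and 0.719 on chromosome 8, with a median of 0.555. Chromosomes differ in gene density, which was not analysed here.

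In the paragraphs that follow, the test on low-control islands and the split of the dip by width of the H3K27ac islands were chosen only after the results they bear on were seen, and the dip by fold was noticed in the data before its tests were run. A pair of hypotheses on candidate enhancers was set down before testing. The first was that they lie closer to H3K4me3 islands than shifted ones. Their median distance was 25.4 kb (quartiles 9.001 and 65.2), below all 1000 circular shifts, whose medians ran from 49.8 to 76.8 kb. Of the candidate enhancers 26.96% lay within 10 kb of an H3K4me3 island and 16.02% beyond 100 kb. The second was that wide H3K4me3 islands have more candidate enhancers within 50 kb. The widest decile had a median of 1 against 0 for the rest, a difference of 1 (two-sided rotation permutation p = 0.001), and a mean of 1.05 against 0.714. Both results are consistent with a clustering of regulatory regions, but the density of islands of any kind along the genome was not held fixed in either test, and the means did not climb evenly: they were 0.782 in the narrowest decile and 0.617 in decile 5.

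The first pattern is the overlap of H3K4me1 with 97.7% of the H3K4me3 islands, centres included, although H3K4me1 is usually described as low at promoter centres. A candidate explanation is that the H3K4me1 antibody also bound H3K4me3, but coverage decides nothing here: H3K4me1 covered the centres of wide H3K4me3 islands 37.5 percentage points more often than the first 1 kb outside, yet H3K27ac, for which no such reaction is proposed, did so by 60.2 points, and H3K4me1 coverage inside was close to its ceiling. In 1350 islands with identical ends in both lists and 40 to 80 control reads per kb, reads per kb of the marks rose together only weakly across islands (Spearman rho 0.193, chromosome draws 0.129 to 0.243; Pearson r 0.203; above 0 on 17 of 22 autosomes; permutation p = 1e-05, the smallest that 100000 permutations can give), which also left it open, between the 0.3 set for the explanation and the 0 set against it. From the lowest to the highest tertile by H3K4me3, median H3K4me3 reads per kb rose 3.90 times and median H3K4me1 reads 1.24 times, nearly all in the first step (278.5, 338.9 and 345.9 per kb), and median width rose as well (1000, 2000 and 2200 bases), which was not held fixed. Neighbouring islands are not independent, so the chromosome draws, and not the permutation p, describe the spread of rho. Control reads still varied within 40 to 80 per kb, and this was not held fixed either. Also open and untested are both marks on neighbouring nucleosomes, mixed cell states in the culture, and islands that bridge a central loss because merging crosses gaps of 400 bases.

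The second pattern is the dip in acetylation at intermediate H3K4me3 fold, where the weakest decile carried H3K27ac 14.4 percentage points more often than decile 4 (chromosome draws 11.4 to 16.9). Island width alone is argued against: among 5998 islands of 1000 to 1600 bases the lowest quintile by fold still stood 19.5 points above the mean of the next pair of quintiles (14.7 to 23.8). Width also ran the other way over all islands. Its median was 1000 bases in the weakest decile and 1400 in decile 4, whereas the share with H3K27ac rose with width. Weak islands as shoulders of stronger ones are argued against too, since 15.1 points remained without islands that had a stronger H3K4me3 island within 2 kb. Leaving out H3K4me3 islands in H3K27ac islands of at least 7 kb left 15.9 points but removes only acetylated islands and so decides nothing, whereas with every island kept, the share that overlapped only narrower H3K27ac islands differed by 13.8 points (10.4 to 16.5) and that in wide ones by 0.604 (-0.858 to 2.42), which argues against wide acetylated domains as the whole cause. What remains open is untested, including weak H3K4me3 at active enhancers in the lowest deciles and promoters held without acetylation in the middle ones, which may be told apart with gene positions.

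The third pattern is that H3K4me3 islands over a sparse control had high folds and mostly lacked the other marks, although the strongest decile by fold as a whole carried H3K27ac in 91.3% and H3K4me1 in 93.2%. Of the 100 islands with the highest fold, 90 had under 10 control reads per kb. The 184 such H3K4me3 islands (0.746%) had a median fold of 63.6 against 15.8 in the others, yet their median of 126 ChIP reads per kb was below the 457 of the others, a difference of -331 (two-sided rotation permutation p = 0.001). H3K27ac overlapped 6.52% of them against 66.7% of the others, and H3K4me1 21.7% against 98.3%. The fold is ChIP over control reads times 1 constant, so their higher median fold came from the small denominator and not from more ChIP reads. The islands were picked by that denominator, so the higher fold is largely built in. Why the control was sparse there is open. Sequence to which few reads map would lower ChIP and control reads alike, and neither this nor a biological explanation was tested.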
